A study of Homo sapiens with 12 samples.

How the data were processed

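Poly-A selected RNA was sequenced from 2 human breast cancer cell lines, MDA-MB-231 and MCF7, each as wild-type cells and as cells in which LHPP had been knocked out with CRISPR-Cas9. Per the labels, cells were grown in DMEM with serum, RNA was extracted with TRIzol and a miniprep kit, and messenger RNA was purified on poly-T beads, fragmented and copied with random hexamers. The labels' protocols mention both strand-marking and unmarked second-strand synthesis, so whether these libraries keep strand is not given in the sources used here. Each of the 4 groups holds 3 libraries, which the labels call biological replicates. Whether they were separate cultures of 1 clone or pool is not given in the sources used here. The p-values therefore measure the spread between these libraries and do not cover differences between clones.

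The authors deposited 1 table per line, with FPKM per gene and library (fragments per kilobase of gene, scaled to library depth), and for MDA-MB-231 also the mean FPKM of each group, which was not used. HISAT2 and the hg38 build are named, without version, in the submitters' processing notes. The read counter, the normalization tool and the annotation release are not given in the sources used here. The listed gene coordinates equalled those of GENCODE release 29 on GRCh38 for 100% of the 28870 genes of the MDA-MB-231 table and of the 58735 genes of the MCF7 table. Of the latter, 29288 were at 0 in every library, and the MDA-MB-231 table listed no such gene. Gene names that a spreadsheet had turned into dates (15 and 17 in the 2 tables) were replaced by the GENCODE symbol of the same identifier.

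Each deposited FPKM value, multiplied by the listed gene length, was a whole multiple of a constant of its library, within a tolerance of 0.01 reads, for 100% of nonzero values. Summed over genes, the recovered reads gave the depth of each library, 14.2 to 18.4 M in MDA-MB-231 and 21.7 to 32.4 M in MCF7. The authors' depth divisor was 0.968 to 1.04 times those sums. FPKM values are not counts, so the test stayed on the log scale. No pair of replicates differed by as little as sampling noise, since the mean chi-square per gene of recovered reads was 2.97 or more in every pair.

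Genes with a mean FPKM of at least 1 over the 6 libraries of a line were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (eBayes with trend and robust settings), and p-values were adjusted by the Benjamini-Hochberg method. A gene was called changed at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, knockout minus wild type, which understates the change of genes near 1 FPKM. Another pseudocount therefore moves the size of such genes more than their call. The tables of the lines were normalized separately, so each line was fitted alone, and the difference between the knockout effects was tested as an interaction term over all 12 libraries, on genes with a mean of at least 1 FPKM in both lines.

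Sets of genes were tested with camera (correlation between genes preset at 0.01, then estimated from the residuals) and fry, both from limma, on 29 fixed lists with at least 5 measured members, and adjusted over the lists. The fry test asks whether the genes of a list move, on balance, 1 way, and does not compare them with other genes. Called members were also counted with the p-values adjusted over the list alone. The groups, tests, lists, first set of alternative settings and the rule for naming genes were set before the data were examined. That rule lets the text name LHPP, the 6 protein-coding genes with the largest rise and the 6 with the largest fall per line among called genes whose groups did not overlap, up to 3 called members per list with the largest change, and a fixed set of line-identity and phosphohistidine-related genes. The text gives a selection of these genes, and other genes named were chosen after their values were seen.

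On simulated data with known changes, the MDA-MB-231 test over 11708 genes recovered 72% of 1.5-fold and 97% of 2-fold changes, with 7.65% false calls. The MCF7 test over 12337 genes recovered 44% and 87%, with 9.03% false calls. The test of the difference over 10099 genes recovered 36% and 87%, with 5.38% false calls. Each of these false-call shares lay above the adjusted-p threshold. The simulation changed 100 genes at each size, while the real tests called 2122 genes in MDA-MB-231 and 990 in MCF7. Whether unequal spread between groups or shifts shared by neighbouring genes alter these percentages was not tested. They describe the simulated data and were not shown to hold for the real calls. Alternatives were a pseudocount of 0.1 or 0.5, no filter or a mean of at least 5 FPKM, median-ratio scaling, rescaling to TPM, rescaling over protein-coding genes without mitochondrially encoded ones, plain eBayes, a replicate block and leaving out each library. A voom fit on recovered reads and a fit with the median effect of each 10-Mb window removed were added after the data were seen.

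Reads of near-identical genes can be split by the counting, so KRT81 and KRT86, HLA-DRB1 and HLA-DRB5, NME1 and NME2, and members of the SPANX family are uncertain as single genes. Of 81 genes examined singly, 13 overlapped the span of another tested gene, mostly on the opposite strand (KRT81, HLA-DPA1, LOXL1, MCAM, ITGB4, NME4, VIM, PHPT1, LAMB1, HK2, PMEPA1, ESR1 and GATA3). Their values could hold reads of the overlapping gene. No variants were analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.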

Results

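Gene expression was measured by RNA sequencing in wild-type and LHPP-knockout cells of 2 breast cancer lines, to learn which transcripts differ when LHPP is knocked out. LHPP is a phosphatase that removes phosphate from histidine and lysine residues and cleaves inorganic pyrophosphate. MDA-MB-231 is a triple-negative line, without oestrogen receptor, progesterone receptor or HER2 amplification, and of mesenchymal (basal B) type. MCF7 is an oestrogen receptor-positive line of luminal type. There were 3 libraries per line and genotype, 12 in all, with 14.2 to 18.4 M recovered reads in MDA-MB-231 and 21.7 to 32.4 M in MCF7. Values are FPKM as mean ± SD with n = 3 libraries per group throughout. Adjusted p-values of genes are from limma with Benjamini-Hochberg adjustment. Each gene named below as risen or fallen had all 3 knockout values on one side of all 3 wild-type values.

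Marker levels separated the lines. VIM, an intermediate filament of mesenchymal cells, stood at 210 ± 10.8 FPKM in wild-type MDA-MB-231, and CAV1, a caveolar protein, at 185 ± 8.04. GATA3, a luminal transcription factor, stood at 201 ± 5.48 FPKM in wild-type MCF7 and at 5.61 ± 0.0966 in wild-type MDA-MB-231. These levels come from tables normalized separately.

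The targeted gene was lower in the knockout of both lines. LHPP (ENSG00000107902, GRCh38 chromosome 10, 124461834 to 124617888, plus strand) fell in MDA-MB-231 from 2.28 ± 0.478 to 0.387 ± 0.041 FPKM (log2 change -1.23 ± 0.14 SE, adjusted p = 0.000485). In MCF7 it fell from 3.43 ± 0.207 to 1.40 ± 0.165 FPKM (log2 change -0.89 ± 0.10 SE, adjusted p = 0.00415). The remaining LHPP transcript was 16.9% of the wild-type level in MDA-MB-231 and 40.9% in MCF7. With a pseudocount of 0.1 the log2 change was -2.28 in MDA-MB-231 and -1.24 in MCF7, and with voom it was -2.53 and -1.29. On log2(FPKM + 1), which understates changes near 1 FPKM, the effect on LHPP was not shown to differ between the lines (interaction adjusted p = 0.16). The lines lay further apart at those other settings, so a similar loss of LHPP in both is not shown. Where the guide cut within the gene is not given in the sources used here.

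**Figure D1:**
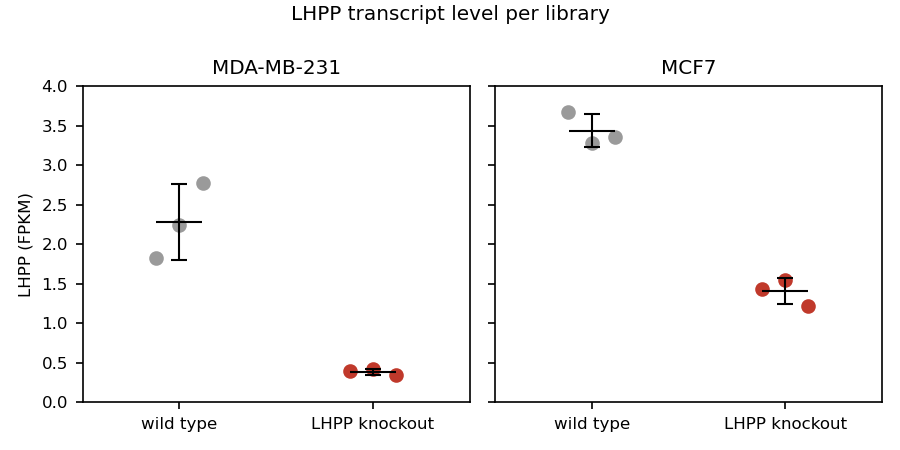
LHPP level (FPKM, vertical axis) in each library of MDA-MB-231 and MCF7, wild type in grey and knockout in red, with the group mean as a horizontal line and the SD of 3 libraries as an error bar. The knockout means are 0.387 FPKM in MDA-MB-231 and 1.40 FPKM in MCF7, against 2.28 and 3.43 in wild type.

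In the LHPP knockout of MDA-MB-231, 10 of 21 measured antigen presentation genes, 7 of 9 luminal markers and 12 of 19 cytokines fell, while matrix genes moved in both directions. With an estimated correlation, 0 of 28 lists passed camera. THBS2, a matrix glycoprotein, rose from 0.193 ± 0.0251 to 9.34 ± 0.844 FPKM (log2 change 3.11, adjusted p = 7.9e-07). PMEPA1, an inhibitor of SMAD signalling that TGF-beta induces, rose from 17.3 ± 0.749 to 102 ± 11.4 FPKM (log2 change 2.48, adjusted p = 1.52e-06). SPDEF, an ETS transcription factor of luminal and secretory epithelium, fell from 12.9 ± 1.5 to 0.237 ± 0.0675 FPKM (log2 change -3.49, adjusted p = 6.71e-07). HLA-DRA, the alpha chain of the HLA-DR antigen-presenting complex, fell from 36.4 ± 2.55 to 7.28 ± 1.43 FPKM (log2 change -2.19, adjusted p = 1.73e-05).

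Of 11708 genes tested in MDA-MB-231, 2122 changed, 891 of them higher and 1231 lower in the knockout. An at least 2-fold change was seen in 245 genes, 65 higher and 180 lower. The groups did not overlap in 39.8% of tested genes, against 10% by chance. Rescaling to TPM, which also brought more genes over the minimum level, gave 1343 higher and 1094 lower. The count was 1061, 1046 and 1014 without wild-type replicates 1, 2 and 3, 3185 without knockout replicate 2 and 1288 without knockout replicate 3.

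The largest other rises in MDA-MB-231 were in HMGN5, a nucleosome-binding protein (0.481 ± 0.141 to 6.57 ± 2.56 FPKM, adjusted p = 0.000307), and PTN, a heparin-binding growth factor (2.67 ± 0.264 to 12.9 ± 3.36 FPKM, adjusted p = 0.000159). IGSF3, an immunoglobulin-family membrane protein, rose from 1.46 ± 0.221 to 7.64 ± 0.966 FPKM (adjusted p = 4.05e-05). Among the largest falls, LGALS12, a galectin, went from 16.1 ± 2.07 to 0.171 ± 0.0553 FPKM (adjusted p = 6.71e-07) and KRT81, a hair-type keratin, from 32.0 ± 4.22 to 2.17 ± 0.198 FPKM (adjusted p = 6.71e-07). PODXL2, a sialomucin, fell from 8.01 ± 0.434 to 0.319 ± 0.181 FPKM (adjusted p = 3.09e-06), and AQP5, a water channel of secretory epithelium, from 6.54 ± 0.389 to 0.158 ± 0.0679 FPKM (adjusted p = 2.26e-06). SPANXB1, a cancer-testis gene, stood at 14.7 ± 1.26 FPKM in wild type and had no read in any knockout library. Set against 3 reads in a knockout library, it was at least 31.9-fold lower (adjusted p = 4.14e-07).

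**Figure D2:**
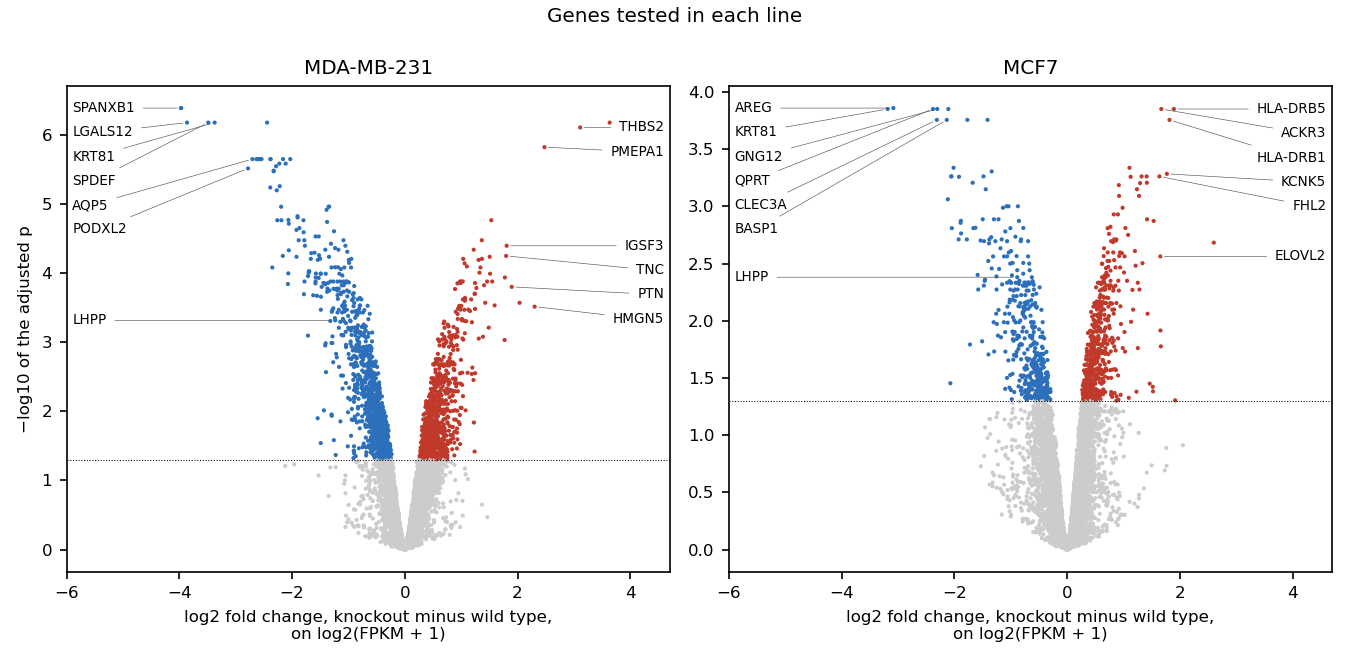
Log2 fold change on log2(FPKM + 1) (horizontal axis, knockout minus wild type) against -log10 of the limma adjusted p (vertical axis) for each tested gene, with genes called higher in red, lower in blue and others in grey. The dotted line marks an adjusted p of 0.05, and the labelled genes are LHPP and the 6 largest rises and falls, among them THBS2 at 3.11 in MDA-MB-231 and KRT81 at -3.18 in MCF7.

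Antigen presentation, luminal and epithelial genes were lower as lists in MDA-MB-231 with the preset correlation of camera. Of 21 measured antigen presentation genes, 10 fell and 11 were not called (12 fell when adjusted over the list alone; median log2 change -0.43, camera adjusted p = 1.16e-06). HLA-DPA1, another class II chain, fell from 4.11 ± 0.126 to 0.582 ± 0.276 FPKM. Of 9 measured luminal line markers, 7 fell (9 adjusted over the list alone; median -0.44, camera adjusted p = 2.8e-06). They included TFF1, an oestrogen-induced trefoil peptide (3.69 ± 0.886 to 0.0352 ± 0.0609 FPKM), and CA12, a membrane carbonic anhydrase (12.8 ± 0.307 to 3.85 ± 0.638 FPKM). Of 10 measured epithelial markers, 5 fell (8 adjusted over the list alone; median -0.39, camera adjusted p = 0.00245), among them the tight-junction gene CLDN3 (3.64 ± 0.177 to 0.787 ± 0.494 FPKM). Each of these camera calls was lost with an estimated correlation, at an adjusted p = 0.441 with an estimated correlation for antigen presentation and luminal markers and 0.455 for epithelial markers. TFF1 lay in a window of chromosome 21, 40 to 50 Mb, whose genes had a median log2 change of -0.49 relative to all genes.

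Cytokine, NF-kB, YAP/TAZ and MYC target genes were also lower as lists in MDA-MB-231 with the preset correlation. Of 19 measured cytokines and chemokines, 12 fell and 1 rose (14 and 2 adjusted over the list alone; median -0.57, camera adjusted p = 3.48e-05). GDF15, a stress-induced TGF-beta family cytokine, fell from 16.5 ± 0.312 to 3.66 ± 0.713 FPKM, and IL11, an interleukin of the IL-6 family, from 5.48 ± 0.675 to 1.34 ± 0.295 FPKM. Of 19 NF-kB response genes, 8 fell (12 adjusted over the list alone; median -0.32, camera adjusted p = 8.09e-05), such as TNFAIP2, induced by tumour necrosis factor (43.3 ± 0.731 to 24.5 ± 1.96 FPKM). Of 22 YAP/TAZ targets, 8 fell and 3 rose (11 and 3 adjusted over the list alone; median -0.25, camera adjusted p = 0.0084). F3, the tissue factor of coagulation, fell from 170 ± 3.08 to 79.5 ± 4.77 FPKM and NUAK2, a kinase, from 4.04 ± 0.568 to 1.37 ± 0.262 FPKM. Of 27 MYC targets, 5 fell (5 adjusted over the list alone; median -0.15, camera adjusted p = 0.0129), and MYC itself fell from 64.5 ± 3.43 to 45.9 ± 3.74 FPKM (log2 change -0.48, adjusted p = 0.00525). Each of these 4 lists had an adjusted p = 0.441 with an estimated correlation.

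TGF-beta response genes and replication-dependent histones were higher as lists in MDA-MB-231. Of 19 TGF-beta response genes, 9 rose and 3 fell (11 and 3 adjusted over the list alone; median 0.30, camera adjusted p = 0.039, adjusted p = 0.476 with an estimated correlation). ID1, a helix-loop-helix inhibitor of differentiation factors, moved against the list, from 52.9 ± 7.02 to 17.9 ± 1.77 FPKM (log2 change -1.51, adjusted p = 6.14e-05). The list missed the threshold without wild-type replicate 3 (adjusted p = 0.0525) and without knockout replicate 2 (0.098), after rescaling to TPM (0.133) or over coding genes (0.0591), with genes of at least 5 FPKM (0.0833) and with windows centred (0.0531). Of 8 measured histone genes, 2 rose (3 adjusted over the list alone; median 0.34, camera adjusted p = 0.0237, adjusted p = 0.441 with an estimated correlation). The histone list missed it without knockout replicate 3 (0.0592) and with windows centred (0.107). The RNA was poly-A selected, and how far that selection shaped the histone values of either line was not tested.

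Some mitochondrial transcripts fell in MDA-MB-231, unevenly across the knockout libraries. Of 13 mitochondrially encoded mRNAs, 4 fell (11 adjusted over the list alone; median -0.39, camera adjusted p = 0.00113, adjusted p = 0.521 with an estimated correlation), among them MT-ND3, a complex I subunit (2629 ± 172 to 1876 ± 201 FPKM). Centring windows removed the MT-ND3 call (adjusted p = 0.295), because mitochondrial genes then lose their shared shift by construction. Mitochondrially encoded genes took 4.28% to 4.47% of reads in the wild-type libraries and 3.02%, 3.61% and 4.15% in knockout replicates 1, 2 and 3. Over the 34 tested genes of the mitochondrial chromosome, MT-ND3 among them, the median log2 difference from the wild-type mean was -0.69, -0.25 and 0.02 in those libraries. Of 33 nuclear-encoded oxidative phosphorylation genes, 8 fell and 2 rose (9 and 2 adjusted over the list alone; median -0.15, camera adjusted p = 0.0349, adjusted p = 0.476 with an estimated correlation). This list missed the threshold without wild-type replicate 3 (adjusted p = 0.0868) and knockout replicate 3 (0.0625), after rescaling to TPM (0.0738) and with genes of at least 5 FPKM (0.0775).

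Matrix, adhesion and growth factor genes moved in both directions in MDA-MB-231. Their lists did not pass camera, though those of adhesion and growth factors did under another setting. Of 28 collagens and matrix glycoproteins, 11 rose and 8 fell (12 and 9 adjusted over the list alone; adjusted p = 0.501). TNC, tenascin C, rose from 8.35 ± 0.191 to 31.9 ± 5.90 FPKM, while COL1A2, a chain of type I collagen, fell from 3.94 ± 0.238 to 0.061 ± 0.0361 FPKM. Of 27 matrix proteases and remodelling enzymes, 10 rose and 5 fell (10 and 5 adjusted over the list alone; adjusted p = 0.229). LOXL1, a collagen cross-linking oxidase, rose from 3.02 ± 0.223 to 9.10 ± 0.986 FPKM (log2 change 1.33), and TIMP3, a metalloprotease inhibitor, fell from 176 ± 2.08 to 74.2 ± 7.91 FPKM. LOXL1 lay in a window of chromosome 15, 70 to 80 Mb, with a median log2 change of 0.50, and its own change was 0.82 with that median removed. Of 19 integrin and adhesion genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.0763, or 0.0465 with voom and 0.0293 with windows centred). ITGB4, the hemidesmosome integrin, rose from 47.9 ± 1.47 to 102 ± 14.8 FPKM, and MCAM, a melanoma adhesion molecule, fell from 11.1 ± 0.263 to 4.03 ± 0.63 FPKM. MCAM lay in a window of chromosome 11, 110 to 120 Mb, with a median of -0.37. Its log2 change was -1.27, or -0.90 with that median removed. Of 21 growth and angiogenic factors, 5 rose and 9 fell (7 and 10 adjusted over the list alone; adjusted p = 0.377, or 0.0394 without a filter). Their median log2 change was 0.000806, or -0.19 after rescaling to TPM, and their mean was -0.17. PDGFB, a platelet-derived growth factor, rose from 1.01 ± 0.0853 to 4.76 ± 0.765 FPKM, VEGFA, the main angiogenic factor, from 15.9 ± 0.562 to 31.5 ± 4.79 FPKM, and the EGF receptor ligand AREG fell from 36.5 ± 2.89 to 6.5 ± 1.78 FPKM.

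Other lists in MDA-MB-231 did not pass camera either, though some did under another setting. Of 32 interferon-stimulated genes, 10 fell and 2 rose (10 and 2 adjusted over the list alone; adjusted p = 0.0507), and LY6E, a membrane-anchored interferon-induced protein, fell from 124 ± 8.99 to 23 ± 2.62 FPKM. The interferon list passed without wild-type replicate 2 (0.0411) or 3 (0.0356) and without knockout replicate 1 (0.0203). It also passed without a filter (0.023), with genes of at least 5 FPKM (0.0159), after rescaling to TPM (0.0338) or over coding genes (0.0434) and with voom (0.0263). Of 36 cell cycle genes, 8 fell and 1 rose (9 and 1 adjusted over the list alone; adjusted p = 0.0507), and MYBL2, a transcription factor of proliferating cells, fell from 44.4 ± 2.20 to 16.9 ± 0.0337 FPKM. The cell cycle list passed without wild-type replicate 2 (0.0433) or knockout replicate 3 (0.0192), without a filter (0.00878), with voom (0.0394) and with windows centred (0.0293). Of 10 mesenchymal markers, 4 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.304), with a rise of TGFBI (17.7 ± 0.236 to 27.6 ± 3.57 FPKM) and a fall of FSTL1 (19.1 ± 0.579 to 7.40 ± 0.323 FPKM). Of 20 basal B line markers, 6 rose and 1 fell (8 and 3 adjusted over the list alone; adjusted p = 0.0763, or 0.0313 without a filter and 0.0465 with voom), and the protease PLAU rose from 133 ± 4.17 to 242 ± 35.2 FPKM. Of 34 hypoxia and glycolysis genes, 5 rose and 9 fell (7 and 10 adjusted over the list alone; adjusted p = 0.519). Of 27 stress response genes, 1 rose and 5 fell (1 and 5 adjusted over the list alone; adjusted p = 0.126, or 0.023 without a filter), among them CHAC1, which degrades glutathione (5.97 ± 0.418 to 2.34 ± 0.253 FPKM). Of 5 measured endothelial and fibroblast markers, 2 fell, COL1A2 and ESAM, an endothelial adhesion molecule (17.8 ± 0.885 to 2.86 ± 0.413 FPKM; 1 rose and 2 fell adjusted over the list alone; adjusted p = 0.102). ESAM lay in a window of chromosome 11, 120 to 130 Mb, with a median of -0.34. Its log2 change was -2.28, or -1.95 with that median removed. Of 2 measured immune cell markers, 1 rose and 1 fell. The adjusted p of camera was 0.429 for sterol and fatty acid synthesis (3 rose, 5 fell), 0.0758 for ribosomal proteins (2 rose, 5 fell; 0.03 and 0.0462 without wild-type replicates 1 and 2, 0.0096 without a filter, 0.0445 with voom and 0.0196 with windows centred), 0.227 for oestrogen response (2 rose, 6 fell) and 0.303 for p53 targets (2 rose, 1 fell).

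Genes of histidine phosphorylation and pyrophosphate turnover, the chemistry of LHPP itself, mostly did not pass the test in MDA-MB-231. Of 18 measured, 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.436). NME4, a mitochondrial nucleoside diphosphate kinase, fell from 16.4 ± 1.12 to 10.4 ± 1.25 FPKM (log2 change -0.61, adjusted p = 0.00471). The histidine kinase NME1 stood at 21.6 ± 0.601 and 18.7 ± 2.00 FPKM in wild type and knockout, and the phosphohistidine phosphatase PHPT1 at 71.2 ± 4.74 and 63.7 ± 5.82. PGAM5, another such phosphatase, stood at 17.7 ± 0.966 and 14.8 ± 1.04 FPKM. The pyrophosphatase PPA1 stood at 20.9 ± 0.718 and 17.6 ± 3.33 FPKM, and passed the test without knockout replicate 1 (log2 change -0.38, adjusted p = 0.0206). By limma, 0 of the 13 measured neighbours of LHPP on 10q26.13 were called, with 1 at an unadjusted p under 0.05 and 0 by voom. With an estimated correlation, 0 of the 28 lists of MDA-MB-231 passed camera, with 0 at an unadjusted p under 0.05, while 16 passed fry.

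In the LHPP knockout of MCF7, 11 of 36 measured cell cycle genes rose and 5 of 22 p53 targets fell, and among the largest changes were those of ACKR3 and KRT81. With an estimated correlation, 0 of 26 lists passed camera. ACKR3, a scavenging chemokine receptor, rose from 51.1 ± 4.48 to 164 ± 3.00 FPKM (log2 change 1.67, adjusted p = 0.00014). HLA-DRB1 rose from 19.0 ± 1.54 to 69.5 ± 6.63 FPKM (log2 change 1.82, adjusted p = 0.000175) and HLA-DRB5 from 6.71 ± 0.425 to 27.7 ± 2.58 FPKM (log2 change 1.89, adjusted p = 0.00014), 2 near-identical genes whose reads may be shared. KRT81 fell from 42.5 ± 7.77 to 3.76 ± 0.535 FPKM (log2 change -3.18, adjusted p = 0.00014). AREG, which oestrogen also induces, fell from 18.2 ± 1.85 to 1.27 ± 0.267 FPKM (log2 change -3.08, adjusted p = 0.000138).

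Of 12337 genes tested in MCF7, 990 changed, 545 higher and 445 lower, and 129 changed at least 2-fold, 42 higher and 87 lower. The groups did not overlap in 30.1% of tested genes, against 10% by chance. The split was 358 higher and 533 lower after rescaling to TPM, 380 and 735 after rescaling over coding genes, and 515 and 211 among genes of at least 5 FPKM. The count was 328 without wild-type replicate 1, 646 without wild-type replicate 2, 322 without knockout replicate 2 and 404 without knockout replicate 3.

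Other large rises in MCF7 were in KCNK5, a potassium channel (11.9 ± 1.90 to 42.5 ± 1.74 FPKM, adjusted p = 0.000518), ELOVL2, a fatty acid elongase (1.00 ± 0.424 to 5.25 ± 0.88 FPKM, adjusted p = 0.00273), and FHL2, a LIM-domain coregulator (3.99 ± 0.624 to 14.5 ± 0.901 FPKM, adjusted p = 0.000546). Large falls were in QPRT, an enzyme of NAD synthesis (5.03 ± 0.171 to 0.161 ± 0.0793 FPKM, adjusted p = 0.00014), and CLEC3A, a C-type lectin (4.74 ± 0.559 to 0.153 ± 0.0445 FPKM, adjusted p = 0.000175). GNG12, a G-protein gamma subunit, fell from 8.25 ± 0.835 to 0.871 ± 0.109 FPKM (adjusted p = 0.00014), and BASP1, a membrane-bound signalling protein, from 53 ± 4.32 to 11.3 ± 1.54 FPKM (adjusted p = 0.000175).

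Cell cycle, hypoxia and MYC target genes were higher as lists in MCF7. Of 36 cell cycle genes, 11 rose (21 rose and 1 fell adjusted over the list alone; median 0.28, camera adjusted p = 5.43e-08, adjusted p = 0.262 with an estimated correlation). MYBL2 rose from 95.9 ± 5.34 to 177 ± 15 FPKM (log2 change 0.87, adjusted p = 0.00194) and E2F1, a transcription factor of S-phase entry, from 25.5 ± 3.05 to 44.2 ± 1.70 FPKM (log2 change 0.77, adjusted p = 0.0049). Of 28 hypoxia and glycolysis genes, 4 rose (9 adjusted over the list alone; median 0.27, camera adjusted p = 0.00119, adjusted p = 0.456 with an estimated correlation). HK2, a hexokinase, rose from 15.9 ± 1.21 to 24.1 ± 1.33 FPKM (adjusted p = 0.00866), a call lost without wild-type replicate 1 (0.0508) or knockout replicate 2 (0.0512). Of 27 MYC targets, 3 rose (4 adjusted over the list alone; median 0.15, camera adjusted p = 0.0168, adjusted p = 0.326 with an estimated correlation). The MYC list missed the threshold with genes of at least 5 FPKM (0.131) and after rescaling over coding genes (0.0933). MYC itself stood at 73.7 ± 3.92 and 92.7 ± 4.63 FPKM (adjusted p = 0.0405). Its call was lost when any 1 library was left out, with adjusted p-values of 0.12, 0.0777 and 0.0657 without wild-type replicates 1, 2 and 3 and 0.0678, 0.167 and 0.115 without knockout replicates 1, 2 and 3.

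Oestrogen response genes in MCF7 mostly rose where they changed. Of 26 measured, 7 rose and 2 fell (9 and 3 adjusted over the list alone; median 0.17, camera adjusted p = 0.0432, adjusted p = 0.509 with an estimated correlation). STC2, a secreted glycoprotein, rose from 23.2 ± 2.52 to 63.2 ± 4 FPKM (log2 change 1.41, adjusted p = 0.000546), while AREG fell. The oestrogen list missed the threshold without wild-type replicate 2 (0.0737) or 3 (0.0962) and knockout replicate 1 (0.0738) or 2 (0.0754), with a pseudocount of 0.1 (0.0511), with genes of at least 5 FPKM (0.354), over coding genes (0.104) and with windows centred (0.0796). ESR1, the oestrogen receptor, rose from 20 ± 0.961 to 27.5 ± 1.08 FPKM (log2 change 0.44, adjusted p = 0.0138), a call lost without wild-type replicate 1 (0.0511) or knockout replicate 2 (0.0787). GATA3 rose from 201 ± 5.48 to 270 ± 6.5 FPKM (log2 change 0.43, adjusted p = 0.00836), a call lost without knockout replicate 2 (0.0587). CA12 rose from 58.1 ± 4.23 to 79.0 ± 0.683 FPKM (adjusted p = 0.0148), a call lost without knockout replicate 2 (0.0789) or 3 (0.069). TFF1 stood at 1055 ± 47.1 and 1034 ± 22.3 FPKM (adjusted p = 0.856). Of 19 luminal line markers, 4 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.255, or 0.00451 without a filter), and BCAS1, a gene often amplified in breast cancer, fell from 10.7 ± 0.102 to 3.21 ± 0.518 FPKM. Of 18 epithelial markers, 1 fell (2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.295, or 0.0144 without a filter).

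The p53 targets, histones, collagens and cytokines were lower as lists in MCF7. Of 22 p53 targets, 5 fell (5 adjusted over the list alone; median -0.24, camera adjusted p = 0.000254, adjusted p = 0.242 with an estimated correlation). BTG2, an antiproliferative gene, fell from 12 ± 0.418 to 5.21 ± 0.476 FPKM (log2 change -1.07, adjusted p = 0.000996). GDF15 fell from 9.02 ± 1.44 to 4.22 ± 0.964 FPKM (adjusted p = 0.0149), a call lost without wild-type replicate 1 (0.0642) or knockout replicate 2 (0.0607) and without a filter (0.0715). By limma, 0 of 8 histone genes were called, with 4 at an unadjusted p under 0.05 and 0 by voom, and the list had a median of -0.33 (camera adjusted p = 0.0168, adjusted p = 0.262 with an estimated correlation). The histone list missed the threshold without a filter (0.0715), after rescaling to TPM (0.172) and with windows centred (0.0568). Of 11 collagens and matrix glycoproteins, 1 rose and 3 fell (1 and 5 adjusted over the list alone; median -0.28, camera adjusted p = 0.046, adjusted p = 0.456 with an estimated correlation). LAMB1, a laminin chain, fell from 19.7 ± 0.277 to 11.1 ± 0.367 FPKM, and EFEMP1, a fibulin, rose from 6.68 ± 0.679 to 17.8 ± 1.05 FPKM. The collagen list missed the threshold without wild-type replicate 1 (0.0798) or 2 (0.158), with a pseudocount of 0.1 (0.0536), with genes of at least 5 FPKM (0.228) and over coding genes (0.0817). Wild-type replicate 2 held more of some collagen and other mesenchymal transcripts than the other MCF7 libraries, such as COL1A2 at 0.817 FPKM against at most 0.00336. COL1A2 was below the minimum level in MCF7 and so was not among the 11 measured. Of 6 cytokines and chemokines, 1 rose and 2 fell (1 and 3 adjusted over the list alone; median -0.28, camera adjusted p = 0.0298, adjusted p = 0.262 with an estimated correlation). The cytokine list missed it without wild-type replicates 1 (0.327), 2 (0.31) or 3 (0.241) or knockout replicate 3 (0.051), after rescaling to TPM (0.103) and with windows centred (0.0568).

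Growth factors, interferon-induced genes and antigen presentation genes moved in both directions in MCF7. Of 14 growth and angiogenic factors, 1 rose and 4 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.598, or 0.0337 with genes of at least 5 FPKM), with a median of 0.08 that TPM rescaling turned to -0.11 and a mean of -0.37. DKK1, a WNT antagonist, fell from 99 ± 13.9 to 23.2 ± 4 FPKM (adjusted p = 0.000546), and BMP7, a bone morphogenetic protein, from 12.7 ± 1.04 to 3.02 ± 0.285 FPKM (adjusted p = 0.000175). PDGFB rose from 9.15 ± 1.53 to 16.9 ± 0.968 FPKM (adjusted p = 0.00866), a call lost without knockout replicate 2 (0.0501). Of 26 interferon-stimulated genes, 2 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.826). Their median was 0.05, or -0.03 after rescaling to TPM, and their mean -0.05. BST2, or tetherin, fell from 110 ± 21.9 to 29 ± 4.14 FPKM (adjusted p = 0.00133) and IFI27 from 22.9 ± 3.93 to 5.46 ± 1.17 FPKM (adjusted p = 0.00139). Of 14 antigen presentation genes, 3 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.621), and TAP2, a peptide transporter, rose from 3.72 ± 0.152 to 5.98 ± 0.202 FPKM (adjusted p = 0.00746). Of 18 matrix proteases and remodelling enzymes, 3 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.323), and TIMP1, a metalloprotease inhibitor, fell from 15.6 ± 1.32 to 8.06 ± 1.03 FPKM (adjusted p = 0.00465).

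Stress response genes were higher as a list in MCF7, with 2 of 24 risen and 1 fallen (8 and 1 adjusted over the list alone; median 0.16, camera adjusted p = 0.0362, adjusted p = 0.262 with an estimated correlation). The stress list missed the threshold without wild-type replicate 1 (0.0548) or 2 (0.0513) or knockout replicate 2 (0.0627), after rescaling to TPM (0.0714) and over coding genes (0.104). Of 16 TGF-beta response genes, 1 rose and 3 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.405), among them PMEPA1 (29.3 ± 1.63 to 19.7 ± 0.246 FPKM, adjusted p = 0.00578). ID1 fell from 127 ± 7.76 to 80.9 ± 12.4 FPKM (adjusted p = 0.0165), a call lost without wild-type replicate 1 (0.0524) or knockout replicate 2 (0.0801) and without a filter (0.0718). Of 17 YAP/TAZ targets, 2 fell (3 adjusted over the list alone; camera adjusted p = 0.429). By limma, 0 of 10 NF-kB response genes were called, with 2 at an unadjusted p under 0.05 and 1 by voom (camera direction down, adjusted p = 0.887, against a median of 0.04 that turned to -0.05 over coding genes). The same test called 0 of 13 mitochondrially encoded mRNAs, with 0 at an unadjusted p under 0.05 and 0 by voom. Their list had a camera adjusted p of 0.314, and passed without wild-type replicate 2 (0.0358) or knockout replicate 1 (0.031). Of 18 genes of histidine phosphorylation and pyrophosphate turnover, 1 rose (camera adjusted p = 0.68). NME1 stood at 20.7 ± 1.49 and 23.1 ± 2.47 FPKM, PGAM5 at 30.1 ± 4.20 and 33.9 ± 1.84, and PPA2, the mitochondrial pyrophosphatase, at 27.8 ± 3.65 and 26.7 ± 1.05. The adjusted p of camera was 0.952 for integrins and adhesion (1 rose, 2 fell, the camera direction being down against a median of 0.02 that turned to -0.08 over coding genes), 0.489 for sterol and fatty acid synthesis (2 fell), 0.387 for ribosomal proteins (1 rose, 1 fell; 0.0478 without knockout replicate 1 and 0.0144 without a filter), 0.429 for nuclear-encoded oxidative phosphorylation (1 rose; 0.0299 without a filter), 0.104 for basal B line markers (1 fell; 0.0173 after rescaling to TPM and 0.000673 without a filter) and 0.826 for the LHPP neighbours (1 rose, with a median of -0.02 against a mean of 0.05). With an estimated correlation, 0 of the 26 lists of MCF7 passed camera, with 4 at an unadjusted p under 0.05, while 9 passed fry.

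**Figure D3:**
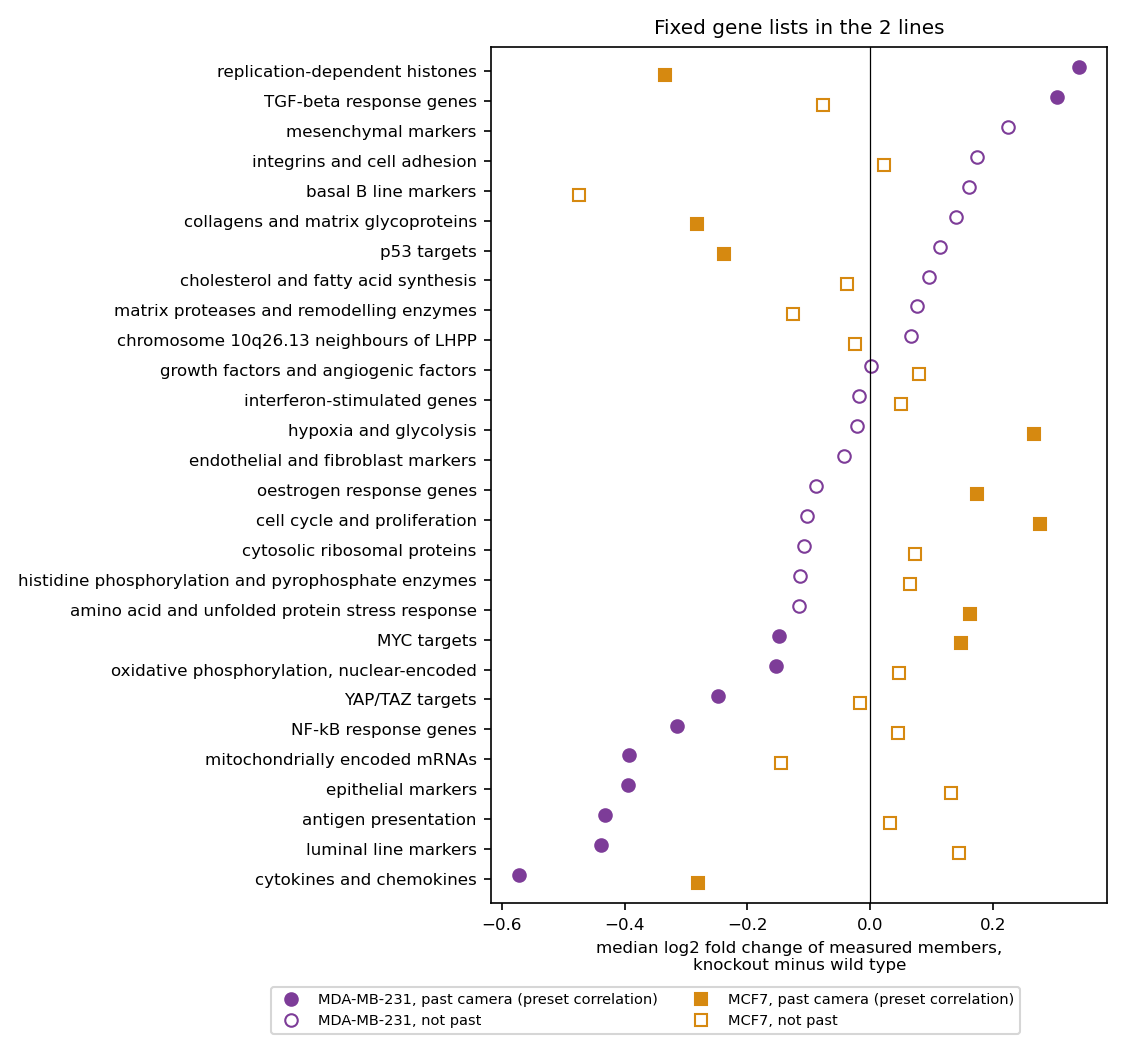
Median log2 fold change of the measured members of each fixed list (horizontal axis, knockout minus wild type), with circles for MDA-MB-231 and squares for MCF7, filled where camera with the preset correlation passed an adjusted p of 0.05. Filled symbols number 11 in MDA-MB-231, such as antigen presentation at -0.43, and 9 in MCF7, such as cell cycle genes at 0.28, and none of these calls held with an estimated correlation.

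The knockout effects of the lines were then compared directly, over the 10099 genes measured in both. ACKR3 fell in MDA-MB-231 (log2 change -2.19) and rose in MCF7 (1.67), and PMEPA1 rose in MDA-MB-231 (2.48) and fell in MCF7 (-0.55). MYBL2 fell by 1.34 on the log2 scale in MDA-MB-231 and rose by 0.87 in MCF7. KRT81 fell in both (-3.37 and -3.18), as did AREG (-2.35 and -3.08), DKK1 (-0.91 and -2.05), BST2 (-0.83 and -1.88) and IFI27 (-0.72 and -1.89). PDGFB rose in both (1.51 and 0.83), though its call in MCF7 was lost without knockout replicate 2 (adjusted p = 0.0501).

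By the interaction test of limma, 1836 genes differed in their response at an adjusted p under 0.05. The signed log2 change in MDA-MB-231 was higher for 677 and lower for 1159. Of the 191 genes called in both lines, 89 moved the same way and 102 the opposite way. Joint falls numbered 54, against 27.5 for independent lists (2-sided Fisher's exact test, adjusted p = 4.6e-06), and joint rises 35 against 29.7 (adjusted p = 0.286). Genes that fell in MDA-MB-231 and rose in MCF7 numbered 72 against 42.9 (adjusted p = 1.6e-05), and the reverse 30 against 19.1 (adjusted p = 0.0204). All of these counts lay above those for independent lists, in the same and in opposite directions, so no single excess shows a shared or an opposed response. Genes are not independent replicates, so these tests describe the lists. Across genes, Pearson's r of the log2 changes was -0.028 and Spearman's rho -0.106. The r was -0.075 without MCF7 wild-type replicate 2, 0.023 without wild-type replicate 3 and -0.070 without knockout replicate 1.

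**Figure D4:**
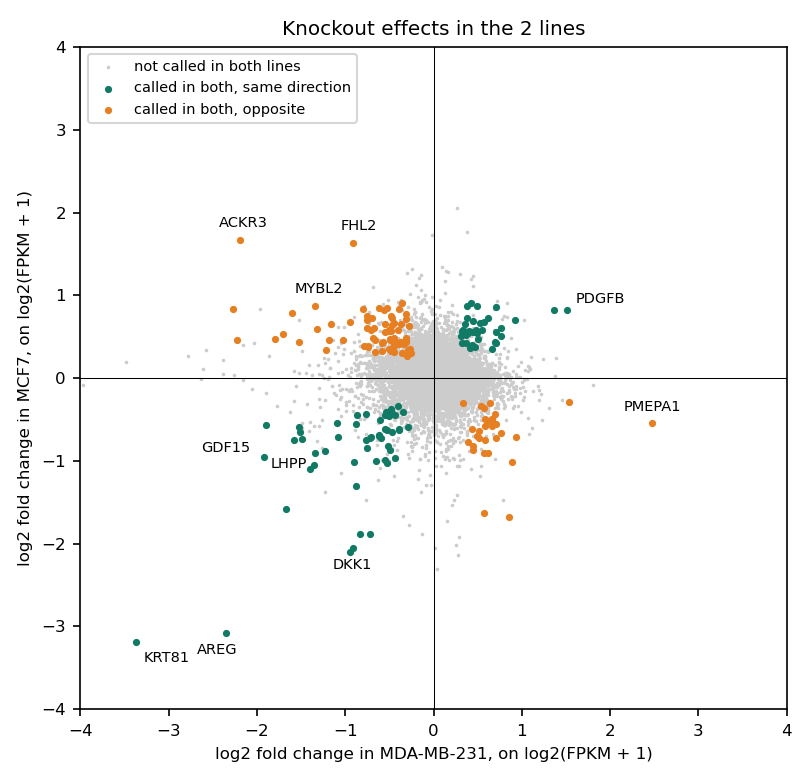
Log2 fold change on log2(FPKM + 1) in MDA-MB-231 (horizontal axis) against that in MCF7 (vertical axis) for 10099 genes, with the 89 genes called in both lines in the same direction in green, the 102 called in opposite directions in orange and all others in grey. KRT81 and AREG lie at the lower left, and ACKR3 and PMEPA1 in opposite corners.

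The response differed between the lines by camera for 7 lists, while 26 of 100 drawn splits of the libraries within the lines gave 7 or more. Luminal line markers had a median of -0.44 over 9 common members in MDA-MB-231 against 0.18 in MCF7 (adjusted p = 4.52e-07, adjusted p = 0.162 with an estimated correlation), and cell cycle genes -0.10 against 0.28 over 36 (adjusted p = 5.68e-06, adjusted p = 0.156 with an estimated correlation). For MYC targets the medians were -0.15 and 0.15 (adjusted p = 0.00133), and for epithelial markers -0.39 and 0.14 (adjusted p = 0.00576). By contrast, histones (0.37 and -0.33, adjusted p = 0.00189) and p53 targets (0.11 and -0.22, adjusted p = 0.0203) were higher in MDA-MB-231. The stress response list (-0.12 and 0.15, adjusted p = 0.0308) missed the threshold without MDA-MB-231 wild-type replicate 3 (0.0512) or knockout replicate 3 (0.0641). With an estimated correlation 0 of 26 lists passed camera, the smallest adjusted p being 0.154, with 4 at an unadjusted p under 0.05, while 18 passed fry.

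Changes were also grouped along the genome. In MDA-MB-231, genes of chromosome 15 between 60 and 100 Mb were higher in the knockout, with window medians of 0.39 to 0.50 on the log2 scale relative to all genes, and 98.5% of the 66 genes between 70 and 80 Mb moved that way. Genes of chromosome 21 between 30 and 50 Mb were lower (-0.44 and -0.49), as were those of chromosome 11 between 110 and 130 Mb (-0.37 and -0.34). In MCF7, genes of chromosome 7 between 30 and 50 Mb were lower (-0.36 and -0.56), as were 95.1% of the 144 genes in the first 10 Mb of chromosome 17 (-0.25), while genes of chromosome 8 between 30 and 40 Mb were higher (0.52). Counting windows of at least 15 genes with a median at least 0.25 from that of all genes and at least 80% of genes on one side, a rule chosen after the windows were seen, gave 14 in MDA-MB-231 and 9 in MCF7. By camera, 31 and 21 windows passed, and other splits of the same libraries gave up to 119 and 102. Over whole chromosomes, camera with an estimated correlation passed chromosomes 15 and 21 in MDA-MB-231 (adjusted p = 0.00378 and 0.00539) and chromosome 7 in MCF7 (0.00338). Chromosome 11 in MDA-MB-231 (0.474) and chromosome 17 in MCF7 (0.968) did not pass. That test was not among those set beforehand and was not run on other splits. With window medians removed, 1627 genes were called in MDA-MB-231 and 659 in MCF7.

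**Figure D5:**
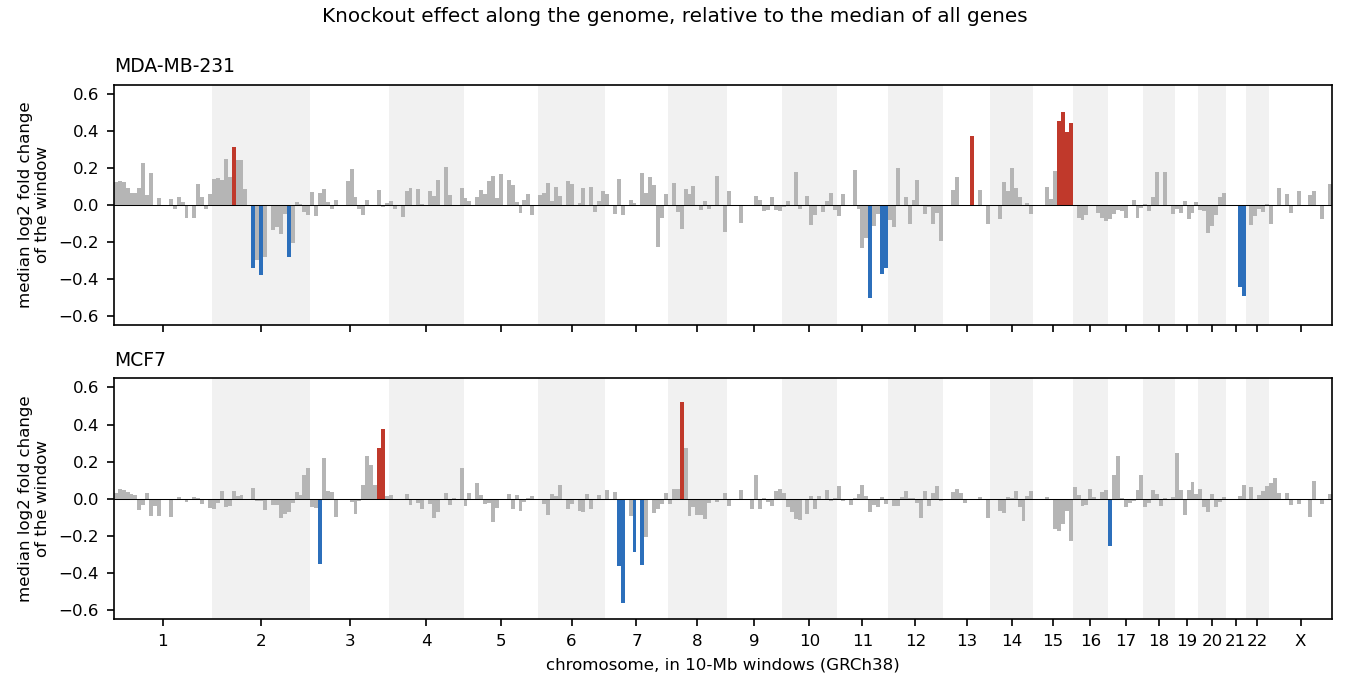
Median log2 fold change of the genes in each 10-Mb window (vertical axis, relative to the median of all genes) along the chromosomes of GRCh38 (horizontal axis) in MDA-MB-231 (top) and MCF7 (bottom), with windows that pass the size rule in red where higher and blue where lower. The red bars of chromosome 15 in MDA-MB-231 reach 0.50, and the blue bars of chromosome 7 in MCF7 reach -0.56.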

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

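The counts of other splits within each line, the tests of the genes lost from the MDA-MB-231 knockout and of the mesenchymal transcripts, and the comparison of windows between the lines were chosen after the results were seen. Groups of 3 libraries are too small for a test of single stray values, so the results here stand out by a difference between the lines, tested as the interaction term of limma with Benjamini-Hochberg adjustment.

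The knockout effect differed for 1836 of 10099 genes. Of 100 drawn splits of the libraries within the lines, 1 gave as many, the real one, and the highest of the others gave 1299. The split with 1299 kept the MDA-MB-231 groups and exchanged those of MCF7. Another kept the MDA-MB-231 groups, mixed those of MCF7 and gave 1076. An effect in 1 line alone can therefore set the real split apart. These splits cannot exclude chance for a difference between the lines. For the lists, chance cannot be excluded: 26 of 100 splits gave 7 or more lists, and the highest other gave 12. The 7 lists were luminal line markers (adjusted p = 4.52e-07), cell cycle (5.68e-06), MYC targets (0.00133), histones (0.00189), epithelial markers (0.00576), p53 targets (0.0203) and stress response (0.0308), each by camera with the preset correlation. With an estimated correlation 0 of the 26 lists passed, the smallest adjusted p being 0.154.

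For several genes the signed log2 change was lower in MDA-MB-231 than in MCF7. The difference of log2 changes, MDA-MB-231 minus MCF7, was -3.87 for ACKR3, -3.68 for SPDEF, -3.11 for IRX5, -3.04 for PODXL2, -2.55 for FHL2, -2.43 for LY6E, -2.22 for MYBL2, -2.14 for TFF1 and -1.96 for CA12. It was -1.57 for CLDN3, -1.48 for TIMP3, -1.34 for DTX3, -1.22 for KISS1, -1.16 for EFEMP1, -1.09 for E2F1, -1.07 for TAP2, -1.06 for HK2 and -1.03 for NME4. Smaller differences were those of GDF15 (-0.97), ID1 (-0.86), MYC (-0.81) and GATA3 (-0.75). FHL2 and EFEMP1 lay in windows of chromosome 2 with medians of -0.34 and 0.31 in MDA-MB-231, and CLDN3 in a window of chromosome 7 with a median of -0.29 in MCF7.

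For other genes the signed log2 change was higher in MDA-MB-231 than in MCF7, which includes genes that fell less there. GNG12 and NR2F2 were not called in MDA-MB-231 (log2 changes 0.03 and 0.26) and fell in MCF7 (-2.30 and -2.01). The difference was 3.03 for PMEPA1, 2.41 for BASP1, 2.34 for GNG12, 2.27 for NR2F2, 2.25 for SERPINE1, 1.89 for IGSF3, 1.32 for TIMP1, 1.17 for IFI27, 1.14 for DKK1 and 1.05 for BST2. It was 0.98 for ITGB4, 0.89 for VEGFA, 0.81 for LAMB1, 0.69 for PDGFB and 0.73 for AREG. The difference of AREG (adjusted p = 0.0388) was lost in 8 of the 12 fits without 1 library, at an adjusted p of 0.0718, 0.0569 and 0.0981 without MDA-MB-231 wild-type replicates 1, 2 and 3, 0.0732 and 0.0644 without knockout replicates 1 and 2, and 0.0943, 0.0848 and 0.0904 without MCF7 wild-type replicate 1 and knockout replicates 2 and 3. That of SERPINE1 (adjusted p = 0.0362) was lost at 0.0735, 0.0709 and 0.069 without MDA-MB-231 wild-type replicates 1, 2 and 3, at 0.0585, 0.0649 and 0.0609 without knockout replicates 1, 2 and 3, and at 0.0576, 0.0726 and 0.0714 without MCF7 knockout replicates 1, 2 and 3. Without MCF7 wild-type replicate 2, SERPINE1 was too low to be tested. NR2F2 lay in a window of chromosome 15 with a median of 0.44 in MDA-MB-231, and its change there was -0.19 with that median removed.

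Within each line, the 6 libraries make 10 splits, too few for a share under 0.05. In MDA-MB-231, 1 split, the real one, reached 2122 changed genes, the highest other giving 0, and likewise 245 genes changed at least 2-fold against 0, 11 lists against 9 and 14 shifted windows against 8. In MCF7, 1 split, the real one, reached 990 genes against 1, 129 against 1, 9 lists against 5 and 9 windows against 1. These window counts use the size rule, which was chosen after the windows were seen and took the place of a count by camera. By camera, the real split of MDA-MB-231 gave 31 windows, against 119, 100, 99, 87, 59 and 36 in 6 other splits, and that of MCF7 gave 21, against 102, 83, 73 and 62 in 4 others. The number of windows by camera therefore does not set the real split apart. Why other splits gave several times its count was not tested.

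Blocks of neighbouring genes that shifted together formed the first pattern weighed. Trends of GC content or gene length are argued against as the whole cause, since 13 of the 14 windows of MDA-MB-231 and 8 of the 9 of MCF7 still shifted the same way after each library was corrected for both. A regional effect of LHPP loss that both lines share is argued against too, because window medians were not positively related across lines (Pearson's r = -0.128) and 0 windows shifted in both by the size rule. A difference in gene dosage between knockout and wild-type cells remains a candidate explanation: genes below the expression filter, which did not define the windows, shifted the same way in 100% of the MDA-MB-231 windows that held enough of them and in 88.9% of those of MCF7. Regional regulation that acts on low genes alike would give the same result, and no DNA data were analysed here.

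The 30 coding genes of any class that fell to 10% or less in the MDA-MB-231 knockout, such as SPANXB1, LGALS12 and SPDEF, formed the second pattern. MCF7 cells in the wild-type libraries are argued against: SPDEF would need 6.82% MCF7 RNA, while 38 genes abundant in MCF7 and near 0 in the knockout stood in wild-type MDA-MB-231 at a median of 0.0761% of their MCF7 level. An effect of LHPP loss that both lines share is argued against for these genes as a set, since of the 18 tested in MCF7 2 also fell there, KRT81 and DTX3, and 4 rose. Among all 12337 genes tested in MCF7, 445 fell and 545 rose, smaller shares in both directions. The MCF7 call of DTX3 was lost without wild-type replicate 1 (adjusted p = 0.111) or 2 (0.0691) and without knockout replicates 1 (0.0533), 2 (0.0872) or 3 (0.0526). It was also lost without a filter (0.0754) and with a replicate block (0.0727). Knockout cells grown from a few cells of a mixed population may have lost genes that a minority of wild-type cells expressed, and these 30 losses stand against 4 coding genes that rose 10-fold or more. In MCF7 the same counts were 12 and 0, so more losses than gains were not particular to MDA-MB-231. Clonal origin and LHPP loss cannot be told apart here, because the labels name no separate clones.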

How the results depend on the processing

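The voom fit and the removal of window medians were chosen after the data were seen. LHPP kept its direction and its call under each alternative in which it was tested, from -2.53 to -1.13 in MDA-MB-231 and from -1.29 to -0.83 in MCF7 on the log2 scale. It was below the minimum in the fit on genes of at least 5 FPKM. The alternatives were run on the genes that the naming rule picked in each line, some of them not named here, on the other named genes where tested and on each tested list. None of these reversed past the threshold: 3868 results stayed on their side of it, 355 lost the call and 51 gained it. Each result is 1 gene or list under 1 setting, called or not in the main fit. By gene, 27 of 107 in MDA-MB-231 and 36 of 95 in MCF7 lost the call under at least 1 alternative. Genes changed at least 2-fold numbered 462 in MDA-MB-231 and 215 in MCF7 with a pseudocount of 0.1, 119 and 43 among genes of at least 5 FPKM, 596 and 279 after rescaling to TPM, and 485 and 233 with voom. Without a filter on low values, 1205 and 407 genes changed and 17 and 14 lists passed. After rescaling over coding genes 5 lists passed in MCF7, and with windows centred 659 genes changed there. The fit on genes of at least 5 FPKM tested fewer genes, 1181 of which differed between the lines. For the other moves the cause was not tested. With 1 library left out, changed genes ranged from 1014 to 3185 in MDA-MB-231 and from 322 to 840 in MCF7, and the correlation between the lines from -0.075 to 0.023. The replicate numbers were not shown to pair the libraries. Same-numbered deviations correlated at 0.151, -0.0748 and -0.0729 in MDA-MB-231 and -0.0632, 0.176 and -0.172 in MCF7, and not every library correlated best with its own number. With 3 libraries per group these values cannot exclude a pairing, and the MDA-MB-231 libraries numbered 1 were each other's best match. A replicate block gave 2616 changed genes in MDA-MB-231 and 492 in MCF7. With the block the MCF7 oestrogen response list missed the threshold (adjusted p = 0.06), as did GATA3 (0.0502), ESR1 (0.0559), CA12 (0.0566), DTX3 (0.0727) and MYC (0.106) there, while the MDA-MB-231 interferon list passed (0.0414). At 14.2 M reads, 3 reads on a gene of 1 kb are 0.212 FPKM, so changes among genes near that level were not detectable.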

Other observations

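The tests and the genes in this part were chosen after the values were seen. Beyond the rule for naming genes, 30 protein-coding genes of MDA-MB-231 fell to 10% or less of a wild-type level of at least 2 FPKM. They included TFF2, a trefoil peptide next to TFF1 (5.16 ± 1.21 to 0.461 ± 0.0285 FPKM, n = 3), and KISS1, the precursor of kisspeptins (2.72 ± 0.428 to 0.211 ± 0.183 FPKM). TFF2 lay in the window of chromosome 21, 40 to 50 Mb, with a median of -0.49. Its log2 change was -2.06, or -1.57 with that median removed. The transcription factor gene IRX5 fell from 3.95 ± 0.423 to 0.0227 ± 0.00244 FPKM in MDA-MB-231 and rose from 35.6 ± 2.86 to 64.1 ± 2.46 FPKM in MCF7. In MCF7, 12 genes stood at 10% or less of wild type, among them NR2F2, an orphan nuclear receptor (3.63 ± 0.0941 to 0.150 ± 0.108 FPKM, adjusted p = 0.000458 by limma with Benjamini-Hochberg adjustment). SERPINE1, the plasminogen activator inhibitor, was also among them but did not pass the test (2.89 ± 3.32 and 0.114 ± 0.043 FPKM, adjusted p = 0.151).

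Mesenchymal transcripts in the MCF7 wild-type library numbered 2 were the third pattern weighed. In that library 25 coding genes stood at least 5-fold above every other MCF7 library, against 0 to 3 in each of the others, with SERPINE1 at 6.70 FPKM, SPARC at 4.98, VIM at 3.74 and CAV1 at 2.08. RNA from MDA-MB-231 cells is argued against as the whole source, since 4 of these genes were more abundant in that library than in wild-type MDA-MB-231 itself: SPARC (0.214 FPKM there), BEX5 (0.118), COL3A1 (0.0342) and GREM1 (0). Whether RNA from fibroblast-type cells was the source stays open. In this library 6 of 22 fixed endothelial and fibroblast markers stood out, fewer than the test asked for, and by the same 5-fold rule that had picked the 25 genes, so this count decides nothing. The wide SD of SERPINE1 in wild-type MCF7 comes from this library.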
